A study of Gallus gallus with 106 samples.

How the data were processed

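Gene expression was measured by targeted RNA-seq in primary satellite cells of broiler Pectoralis major, kept at 1% or 20% O2 through 48 h of differentiation. Per the labels' protocols, RNA was isolated with a Direct-zol kit and reverse transcribed, and primers for a panel of chicken RefSeq transcripts were designed so that products span exon boundaries. The authors deposited one table of raw read counts with 590 transcripts and 106 samples, which are 53 biological libraries in 2 technical replicates each. The genome build is galGal6, per the submitters' processing notes, and the coordinates are those of the deposited table; the aligner and counter are not given in the sources used here. The panel was chosen by the study, and CPM of different amplicons are not comparable. MYMK, MKI67, CDK1, LDHA and MYC are not analysed here.

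In all 1160 cells in 21 columns were blank and were read as 0. In 11 of these columns no 0 was written at all, and in 10 columns only the last 2 transcripts were blank. Technical replicate 1 of normoxia 0 h replicate 1 held neither a blank nor a 0. All its 590 transcripts were above 0, against at most 516 in any other column, and why was not tested. The 2 transcripts of 21 genes were summed, which gave 569 genes. Gene names are those of the deposited table, checked against a RefSeq gene table of assembly GRCg7b that served for names alone. Of the names 522 matched a current symbol and 4 an older one, among them GDF8 for MSTN. A further 31 Ensembl-only names had no match (0 of 31) and 12 other names were kept. Value columns that matched no sample numbered 0. Technical replicates were summed per biological library. Their totals ran from 76735 to 739169 counts, and the totals of biological libraries from 171196 to 1448544. The median SD of log2 CPM was 0.242 between single technical replicates, scaled by their totals. It was 0.241 between the summed biological libraries of a group, which were also scaled by TMM factors, and this SD was the larger in 274 of 453 genes. Sums of 2 replicates carry less technical spread than single ones, so the 2 values do not show that libraries differ no more than technical replicates. The 10 genes with most counts took 9.7% of all counts. The labels state no molecular identifiers, so reads are not taken as independent molecules.

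Counts were scaled by TMM factors and tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with all 9 groups in the fit. Of 569 genes 453 passed filterByExpr and 116 did not. Calls are at a Benjamini-Hochberg adjusted p of 0.05 over the 453 genes. The common biological coefficient of variation was 26%, with 44 residual degrees of freedom and a median prior of 4.8. SE is the log2 change divided by the square root of F. The comparisons were hypoxia with normoxia at 12, 24, 36 and 48 h, the difference of these effects between times, 48 h with 0 h in each oxygen level, and any change over time in normoxia. All adjusted p-values of genes are from edgeR unless DESeq2 1.42.0 is named.

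Gene lists were fixed before the data were examined, as were the comparisons, tests, most alternatives and the rule for named genes. In each of 6 contrasts 21 lists with at least 3 tested members were tested with fry of limma 3.58.1, adjusted over the lists of the contrast. Its directional p tests whether the genes of a list move one way on balance, and its mixed p whether they change in either direction; neither compares the list with other genes. The fusion, cell cycle inhibition and proteolysis lists had too few tested members. The lists cover identity, myogenic factors and their inhibitors, contractile genes, proliferation, HIF targets, glycolysis, mitochondria, IGF, TGF-beta, FGF and PDGF, Notch, Wnt, matrix, lipid, autophagy, antioxidant, apoptosis, stress, other-cell marker and reference genes.

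Named genes are the 10 highest and 10 lowest log2 changes among called genes in each hypoxia contrast, 6 and 6 from 0 to 48 h, the 6 smallest p-values of the difference between times, a fixed set of myogenic, cell cycle, hypoxia and growth factor genes, and the members with the largest changes of each list described. Genes called at every time, genes called in both directions, and other list members named because they passed were chosen after their values were seen.

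The procedure was tested on simulated data with 445 genes. For hypoxia at 48 h it recovered 63.1% of 65 genes changed 1.5-fold, 89.4% of 66 changed 2-fold and 100% of 63 changed 4-fold, and it called 2 unchanged genes. For the difference between times the shares were 55.4%, 77.3% and 90.5%. The simulated genes varied independently of each other, without the variation shared by many genes that the real libraries show. The shares recovered and the few false calls may therefore not hold for the real data. Alternatives were DESeq2, scaling by library totals or by 6 reference genes, no filter, each technical replicate alone, the biological number as a replicate block, a fit of the compared groups alone, and leaving out each biological number in turn. After seeing the data 5 were added: each transcript on its own, leaving out the libraries in which a set of 17 genes was raised, the score of that set as a covariate, leaving out its genes, and leaving out hypoxia 36 h replicate 4. The set holds the genes correlated above 0.8 with the first component of the variation within groups, which carries 31.9% of that variation.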

Results

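The data were counts from targeted RNA-seq, in which a fixed panel of transcripts is amplified from cDNA and sequenced, of primary satellite cells from the breast muscle (Pectoralis major) of wild-type broiler chickens. Satellite cells are the muscle stem cells that divide, differentiate and fuse to form muscle fibres. The cells were moved to differentiation medium and kept for 48 h at 1% O2 (hypoxia) or 20% O2 (normoxia), and cells were harvested at 0 h, before the medium change, and every 12 h after it. There were 5 biological libraries at 0 h and 6 for each oxygen level at 12, 24, 36 and 48 h, 53 in all, each measured in 2 technical replicates that were summed. The total count per biological library ran from 171196 to 1448544, with a median of 759253, and group medians ran from 601750.5 in hypoxia at 48 h to 1064169 in normoxia at 0 h. The panel covered 569 genes chosen by the study, of which 453 had enough counts to be tested. Levels are normalised read counts (CPM, counts scaled by library size in edgeR) as mean ± SD over the libraries of a group, and changes are log2 values with their standard error (SE). CPM of different genes reflect primer yield and are not compared with each other. The labels do not say that the libraries came from separate birds, so p-values measure only the spread between these samples, which may be technical.

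One feature of the libraries bears on several comparisons. A set of 17 genes, among them MC5R, SSTR2, HRH2, THRSP, FBP2 and IRS1, rose and fell together within groups. Their score, the mean log2 CPM, left a gap between 6.48 and 7.55, and 17 of the 53 libraries lay above it. Those libraries were 1 of 5 in normoxia at 0 h, 4 of 6 at 12 h, 1 of 6 at 24 h, 1 of 6 at 36 h and 5 of 6 at 48 h. In hypoxia they were 1 of 6 at 12, 24 and 36 h and 2 of 6 at 48 h.

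**Figure D1:**
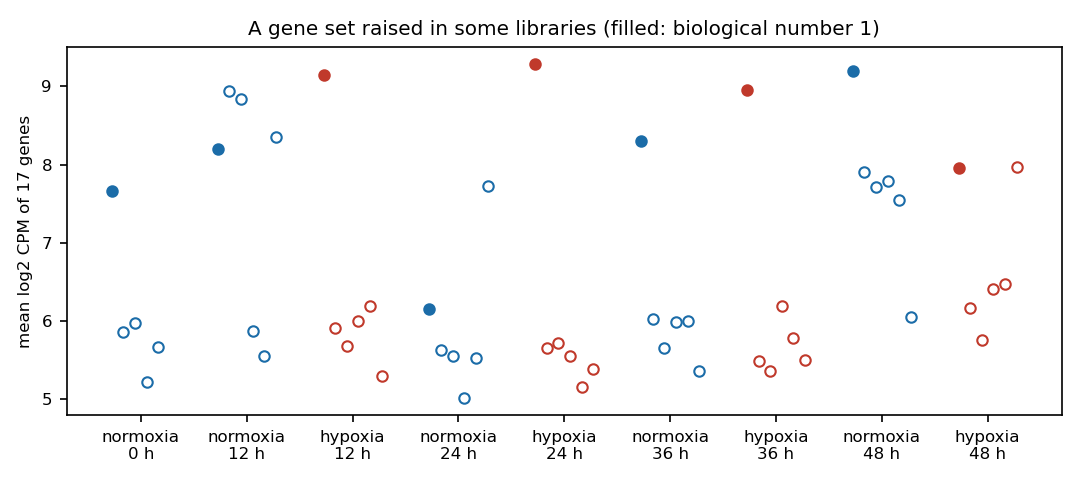
Score of the 17 genes (mean log2 CPM, vertical axis) in each of the 53 biological libraries, by group, with filled points for the libraries carrying biological number 1. The libraries above the gap from 6.48 to 7.55 include 5 of the 6 normoxia libraries at 48 h and 2 of the 6 hypoxia libraries at 48 h.

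The course of differentiation in normoxia was described by comparing 48 h (n = 6) with 0 h (n = 5). SPON2, a secreted extracellular matrix protein, rose from 16.7 ± 6.35 to 347 ± 36.2 CPM (log2 4.43, SE 0.26), and PTGDS, which makes prostaglandin D2, rose from 159 ± 41.8 to 2439 ± 270.4 CPM (log2 3.96, SE 0.20). The fatty acid-binding protein FABP1 (log2 3.89), the matrix protein DPT (2.92), the secreted lipocalin EXFABP (2.72) and the growth factor FGF18 (2.67) rose as well. MSTN, which encodes myostatin, an inhibitor of muscle growth, fell from 1604 ± 147 to 151 ± 31.3 CPM (log2 -3.41, SE 0.31). The largest falls besides MSTN were in WNT4 (log2 -4.60), the matrix metalloproteinase MMP9 (-3.85), the endothelial marker VWF (-3.64), endothelin EDN1 (-3.20) and the Notch target HEY1 (-3.02). Between 0 and 48 h, 184 of 453 genes changed, 70 higher and 114 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 181 lay on the same side of the 0 h mean in 6 of 6 libraries at 48 h.

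Several muscle structural genes rose in the same period. Of 11 tested contractile and structural genes 6 rose, 0 fell and 5 did not pass, and the count adjusted over the list alone was also 6 (fry, list adjusted p = 2.27e-17). The Z-disc gene LDB3 went from 805 ± 172 to 3830.1 ± 269 CPM (log2 2.26, SE 0.14) and the myosin heavy chain MYH1D from 1297 ± 295 to 4845 ± 237 CPM (log2 1.92, SE 0.08). MYH1D already stood at 4085 ± 134 CPM at 12 h. The chicken fast myosin genes are close copies of each other and how reads were assigned among them is not given in the sources used here, so the gene behind each MYH1 value is uncertain. The master regulators of myogenesis showed no such rise, with MYOD1 at 4236 ± 429 and 4027 ± 535 CPM (log2 -0.07, adjusted p = 0.618) and MYOG at 4682 ± 191 and 4582 ± 617 CPM (log2 -0.03, adjusted p = 0.857). The satellite cell factor PAX7 had a log2 change of -0.06 (adjusted p = 0.826). Of the 7 myogenic regulatory factors 1 rose, 1 fell (MYF5, an early determination factor, log2 -0.85, SE 0.21) and 5 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.385).

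The satellite cell identity, proliferation, myogenic inhibitor, Notch, FGF and PDGF receptor and Wnt lists were called downward. Of 7 satellite cell identity genes 1 rose, 4 fell and 2 did not pass, with the same counts adjusted over the list alone (Down, adjusted p = 1.1e-07). The laminin receptor ITGA7 rose by 2.32 and the transcription factor PAX3 fell by 1.84 on the log2 scale. Of 5 proliferation genes 4 fell, also adjusted over the list alone (adjusted p = 1.93e-12): the cell cycle activator E2F1 (log2 -2.18), the nucleotide reductase subunit RRM2 (-0.31), the replication clamp PCNA (-0.21) and CCND1, cyclin D1 (-0.15). HEY1 and MSTN fell among 3 inhibitors of myogenic factors (adjusted p = 5.51e-19; 2 adjusted over the list alone). Of 3 Notch genes 2 fell, HEY1 and the receptor NOTCH1 (log2 -1.79), again 2 adjusted over the list alone (adjusted p = 1.17e-08). In the FGF and PDGF receptor list 4 of 6 fell, also adjusted over the list alone (adjusted p = 7.51e-06), led by FGFR3 (log2 -1.18) and FGFR4 (-0.95). In the Wnt list 1 of 7 rose and 3 fell, the same adjusted over the list alone (Down, adjusted p = 4.42e-10), with WNT4 and WNT5B (log2 -2.20) furthest down.

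Of 22 lipid genes 6 rose, 0 fell and 16 did not pass (5 adjusted over the list alone; Up, adjusted p = 6.37e-06), led by the apolipoprotein APOA1 (log2 2.24) and the fatty acid transporter CD36 (1.71). Insulin-like growth factors went apart: IGF2 rose from 770.5 ± 278 to 3601 ± 187 CPM (log2 2.23, SE 0.28) and IGF1 fell by 1.98 on the log2 scale (SE 0.28). Of the 11 IGF and insulin genes 3 rose, 3 fell and 5 did not pass, the same adjusted over the list alone (on balance adjusted p = 0.337, change in either direction adjusted p = 7.17e-05). The mitochondrial list behaved likewise, with 3 of 13 higher and 4 lower (5 lower adjusted over the list alone), a median of -0.25 against a mean of 0.06, and adjusted p-values of 0.295 on balance and 3.37e-12 in either direction. In the TGF-beta list 3 of 12 rose and 4 fell, the same adjusted over the list alone (Down, adjusted p = 3.1e-07), with a mean of -0.44 against a median of 0.03. MSTN and TGFB1 (log2 -1.77) fell furthest there. Of 18 matrix and fibroblast genes 4 rose, 3 fell and 11 did not pass (5 and 3 adjusted over the list alone; on balance adjusted p = 0.616, in either direction 0.00048).

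Among smaller lists, 3 of 7 antioxidant genes fell, also adjusted over the list alone (adjusted p = 2.06e-05), led by thioredoxin reductase TXNRD1 (log2 -0.95) and the metallothionein MT3 (-0.66), while the list's median was 0. Of 5 apoptosis genes the death receptor FAS rose (log2 1.02) and CASP9, which starts the mitochondrial death pathway, fell (-1.02), 1 each adjusted over the list alone, and the list was called upward (adjusted p = 0.000623). Of 4 endothelial, immune and blood cell markers VWF and CDH5 (log2 -1.32) fell, 2 adjusted over the list alone (adjusted p = 1.55e-07). No call came from the HIF pathway list (0 of 5 genes, adjusted p = 0.795), autophagy (0 of 3, 0.573) or heat shock and ER stress (0 of 3, 0.174), where edgeR gave 0 genes at an unadjusted p under 0.05 and DESeq2 called 0. Glycolysis had 1 of 11 lower, HK2, 1 adjusted over the list alone (adjusted p = 0.768). Without the 17 libraries above the gap in the 17-gene score, which leaves 1 normoxia library at 48 h, 68 genes were called, 3 of the 184 had the other direction, and CDH5, 1 of these 3, had a log2 change of 0.36 (adjusted p = 0.822). The TGF-beta, FGF, Wnt, antioxidant and marker lists were then not called (adjusted p = 0.323, 0.175, 0.0608, 0.29 and 0.103). Scaling to reference genes ended the calls of the TGF-beta, antioxidant and apoptosis lists (adjusted p = 0.56, 0.661 and 0.261) and those of PCNA and CCND1 (0.154 and 0.129). Leaving out 1 replicate ended the calls of CCND1 (replicate 1, 3 or 5, adjusted p up to 0.109), CASP9 (2 or 5, up to 0.118) and CDH5 (2, 3 or 5, up to 0.098).

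**Figure D2:**
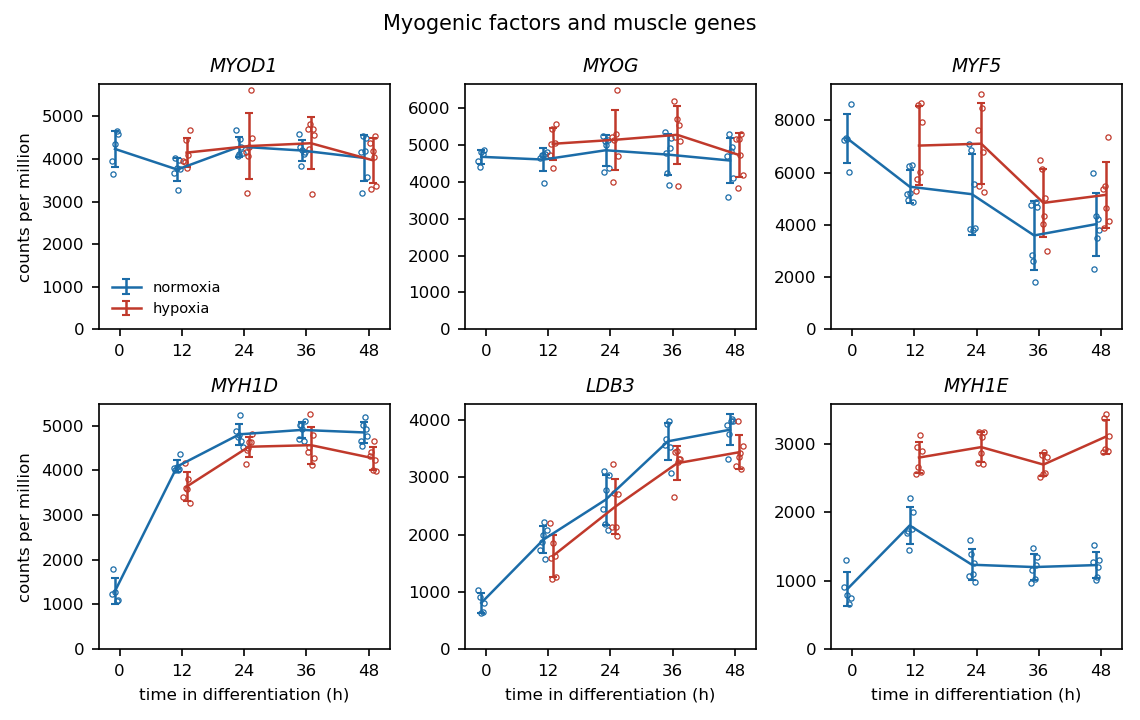
Normalised read counts (CPM, vertical axis) against hours in differentiation (horizontal axis) for 3 myogenic factors and 3 muscle genes, with points for libraries, lines for group means and bars for the SD, normoxia in blue and hypoxia in red. MYOD1 and MYOG stayed near their 0 h level of 4236 and 4682 CPM, MYH1D and LDB3 rose, and MYH1E stood at 3101 CPM in hypoxia against 1227 CPM in normoxia at 48 h.

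A test over all 5 harvests in normoxia asked which genes moved at any time and found 271 of 453 (293 at an unadjusted p under 0.05). MYH1D (adjusted p = 2.27e-26), SPON2 (3.21e-24) and PTGDS (2.29e-23) had the smallest p. Their courses differed in time, since MYH1D had made most of its rise by 12 h, while SPON2 stood at 19.5 ± 4.76 CPM at 12 h, 104 ± 32.2 at 24 h and 288 ± 48.0 at 36 h. The count was 147 without the 17 libraries above the gap in the 17-gene score, and 11 of the 17 genes were among the 271.

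The comparison of hypoxia with normoxia at each harvest asked how low oxygen changed the cells during differentiation. At 12 h (n = 6 against 6), EXFABP rose from 122 ± 40.4 to 1458 ± 215 CPM, 12.1-fold (log2 3.60, SE 0.17, edgeR adjusted p = 1.07e-23). EXFABP lies on chromosome 17 at 865358 to 868425 of galGal6, a gene of 7 exons on the minus strand. COCH, the matrix protein cochlin (chromosome 5, 34450679 to 34467653, 11 exons), rose from 219 ± 69.2 to 928 ± 229 CPM (log2 2.09, SE 0.27). MSTN, named GDF8 in the deposited table (chromosome 7, 252348 to 257840, 3 exons), fell from 438 ± 91.1 to 86.9 ± 26.9 CPM (log2 -2.34, SE 0.30), and IGF2 (chromosome 5, 13971786 to 13980128, 3 exons) from 1414 ± 277 to 608 ± 202 CPM (log2 -1.23, SE 0.26). The chemokine CCL5 fell from 41.6 ± 17.3 to 4.56 ± 4.34 CPM (log2 -3.36, SE 0.53) while the chemokine CCL20 rose from 4.61 ± 4.81 to 22.7 ± 4.22 CPM (log2 2.15, SE 0.51). The lower level of each chemokine rests on few reads.

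Further genes that rose at 12 h were the fibril-associated collagen COL12A1 (log2 1.73), the glycolytic enolase ENO1 (1.34, 28.9 ± 7.32 to 72.5 ± 13.8 CPM), the calcium buffer PVALB of fast muscle (1.32), the transcription factor KLF9 (1.25), the receptor FGFR3 (1.06), the retinol carrier RBP4A (0.92) and hexokinase HK2 (0.81). The falls included the tumour necrosis factor receptor TNFRSF1B (log2 -2.06), the fatty acid elongases ELOVL4 (-1.95) and ELOVL1 (-1.76), the retinoic acid receptor RARB (-1.88), the angiotensin receptor AGTR2 (-1.78), the myosin light chain kinase MYLK (-1.67) and neuropeptide Y, NPY (-1.43). A gene known only as ENSGALG00000012061 fell from 648 ± 73.2 to 157 ± 25.7 CPM (log2 -2.05). The cell cycle inhibitor CDKN1A, the one tested member of the cell cycle inhibition list, fell by 0.52 (SE 0.14, adjusted p = 0.00504). MYOD1 (log2 0.14), MYOG (0.13), PAX7 (0.17), MYF5 (0.37), MYF6 (-0.82), PCNA (0.00), CCND1 (0.09), HIF1A (-0.08), VEGFA (0.09), PDK1 (0.16), SLC2A1 (0.07) and IGF1 (-0.50) did not pass.

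Of the 21 gene lists 5 were called at 12 h. Of 11 glycolysis and lactate genes 2 rose, ENO1 and HK2, 0 fell and 9 did not pass, with 2 adjusted over the list alone (Up, adjusted p = 8.45e-05). In the mitochondrial list 3 of 13 fell, also adjusted over the list alone (Down, adjusted p = 0.00354), with PPARGC1A, a coactivator of mitochondrial biogenesis, at -0.83 and the nuclear receptor PPARD at -0.82. Of 11 contractile genes 3 rose and 8 did not pass (3 higher and 1 lower adjusted over the list alone; Up, adjusted p = 0.000413), led by PVALB and MYH1E (0.63, SE 0.12). TNNT2, with the largest value of the list (1.44), did not pass (adjusted p = 0.197). All 3 inhibitors of myogenic factors changed, also adjusted over the list alone (Down, adjusted p = 8.45e-05): MSTN and HEY1 (-0.64) fell and BHLHE40, a hypoxia-induced repressor, rose (0.24). In the lipid list 1 of 22 rose, ACACA, which makes malonyl-CoA (0.78), with 1 adjusted over the list alone (Up, adjusted p = 0.0119), and CEBPB was at 0.41 (adjusted p = 0.332).

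In all, 81 of 453 genes changed at 12 h, 34 higher and 47 lower (160 at an unadjusted p under 0.05). Of these, 77 of the 81 lay on one side of the normoxia mean in 6 of 6 hypoxia libraries, with KLF9 in 5 of 6. The libraries above the gap in the 17-gene score were 4 of 6 in normoxia and 1 of 6 in hypoxia at this time. Without them 24 genes were called, with 2 normoxia libraries left. Scaling to reference genes gave 42 genes, 9 higher and 33 lower. DESeq2 gave 26 higher and 63 lower, and the median change of all genes was -0.078 with reference genes against 0.042. Technical replicate 1 alone gave 47 genes, a fit of these groups alone 131, and leaving out replicate 2, 3 or 6 gave 48, 45 and 44. With reference-gene scaling the contractile, glycolysis, mitochondrial and lipid lists were not called (adjusted p = 0.573, 0.282, 0.102 and 0.784), nor were FST (0.54) and HK2 (0.192). Without the libraries above the gap the contractile and lipid lists were lost (0.214 each). Leaving out 1 replicate ended the calls of HK2 (replicate 2, 3, 5 or 6, adjusted p up to 0.0827), KLF9 (1 to 5, up to 0.172), COL12A1 (3, 4 or 6, up to 0.143), PPARD (1, 2, 3, 4 or 6, up to 0.146), RARB (2, 3 or 6, up to 0.0676) and HEY1 (1, 2, 3 or 6, up to 0.104). It also ended those of ACACA (3 or 6, up to 0.0591), FST (1 or 5, up to 0.0729), BHLHE40 (1 or 3, up to 0.0522) and the lipid list (6, 0.0879).

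At 24 h (n = 6 against 6) EXFABP stood at 2329.5 ± 205 CPM in hypoxia and 223 ± 57.3 in normoxia (log2 3.41, SE 0.17, edgeR adjusted p = 8.29e-23) and COCH at 1267 ± 459 and 151 ± 36.5 CPM (log2 3.07, SE 0.28). The cytokine IL6 rose from 998 ± 163 to 3028 ± 568 CPM (log2 1.61, SE 0.15, adjusted p = 1.22e-12). FST, follistatin, which binds and blocks myostatin and activin, rose from 3186.5 ± 413 to 5917 ± 694 CPM (log2 0.90, SE 0.08, adjusted p = 7.58e-13). MSTN stood at 42.5 ± 27.2 CPM in hypoxia and 241 ± 73.5 in normoxia (log2 -2.53, SE 0.31), and IGF2 at 643 ± 280.4 and 2216 ± 792 CPM (log2 -1.79, SE 0.27). SPON2, which rose during differentiation in normoxia, was at 21.8 ± 5.71 CPM in hypoxia against 104 ± 32.2 (log2 -2.29, SE 0.23).

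Other rises at 24 h were in CCL20 (log2 2.80), the late myogenic factor MYF6 (2.02, SE 0.68, adjusted p = 0.0303), ENSGALG00000041298 (1.85), PVALB (1.59), endothelin EDN2 (1.58), the muscle calpain CAPN3 (1.38) and ENSGALG00000030587 (1.29). CAPN3 was the one tested member of the proteolysis list. Falls besides those named were in ELOVL4 (log2 -3.22), ELOVL3 (-3.07), ENSGALG00000012061 (-2.48), the alkaline phosphatase ALPL (-2.33), TNFRSF1B (-2.03), the glypican GPC3 (-1.78) and FABP1 (-1.71). VEGFA, the angiogenic target of HIF, rose by 0.15 (SE 0.05, adjusted p = 0.0459). MYOD1 (log2 0.01), MYOG (0.08), PAX7 (0.12), MYF5 (0.45), PCNA (-0.03), CCND1 (0.12), CDKN1A (-0.09), HIF1A (-0.02), PDK1 (-0.01), SLC2A1 (0.22) and IGF1 (-0.06) did not pass.

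The test called 7 lists at 24 h on balance. Of 4 endothelial, immune and blood cell markers IL6 and VWF (log2 0.98) rose and 2 did not pass, with 2 adjusted over the list alone (Up, adjusted p = 3.83e-06); satellite and muscle cells are known to make IL6 themselves. Of 11 contractile genes MYH1E (1.26, SE 0.12) and PVALB rose and 9 did not pass, with 2 adjusted over the list alone (Up, adjusted p = 0.00125). In the mitochondrial list 1 of 13 rose, 4 fell and 8 did not pass (5 lower adjusted over the list alone; Down, adjusted p = 0.00787), led by PPARGC1A (-1.07) and the uncoupling protein UCP3 (-0.92). Of 7 identity genes PAX3 (1.12) and the adhesion molecule NCAM1 (0.25) rose, 2 adjusted over the list alone (Up, adjusted p = 0.0361). HK2 (1.27) led 2 of 11 glycolysis genes that rose, 2 adjusted over the list alone (Up, adjusted p = 0.0456), and ENO1 was at 0.33 (adjusted p = 0.537). Among 3 stress genes the ER kinase EIF2AK3 rose (0.58), 1 adjusted over the list alone (Up, adjusted p = 0.00125), with the ER stress sensor ATF6 at 0.09. In the Wnt list WNT5A fell (-0.88, SE 0.11) and 6 of 7 did not pass, 1 adjusted over the list alone (Down, adjusted p = 0.0361), with a mean of -0.12 against a median of 0.02. In the TGF-beta list 1 of 12 rose and 2 fell, the same adjusted over the list alone; on balance its adjusted p was 0.64 (Up, median 0.03, mean -0.17) and in either direction 7.35e-05, with FST and MSTN moving apart.

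At 24 h 84 of 453 genes changed, 45 higher and 39 lower (126 at an unadjusted p under 0.05). Of these, 63 of the 84 lay on one side of the normoxia mean in 6 of 6 hypoxia libraries. A fit of these groups alone called 42, technical replicates 1 and 2 alone 55 and 49. With reference-gene scaling the identity, contractile, glycolysis, mitochondrial, Wnt and stress lists were not called (adjusted p = 0.106, 0.106, 0.106, 0.483, 0.626 and 0.161). The identity, glycolysis and Wnt lists were also lost without the libraries above the gap in the 17-gene score (0.163, 0.12 and 0.141). VEGFA and EIF2AK3 kept their calls in 7 and 6 of 19 alternative settings. Leaving out 1 replicate ended the calls of VEGFA (replicate 1, 3, 5 or 6, adjusted p up to 0.327), EIF2AK3 (1, 2, 3, 4 or 6, up to 0.191), MYF6 (1, 2 or 5, up to 0.112), UCP3 (2, 3, 5 or 6, up to 0.326), VWF (1 or 2, up to 0.0746) and NCAM1 (each of the 6, up to 0.123). Among the lists it ended those of glycolysis (1, 2, 3, 5 or 6, up to 0.203), Wnt (2, 3, 4 or 6, up to 0.0915), identity (2, 4 or 6, up to 0.138) and mitochondria (6, 0.0743).

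At 36 h (n = 6 against 6) COCH was at 1294 ± 536 CPM in hypoxia and 173 ± 60.3 in normoxia (log2 2.88, SE 0.28), and EXFABP at 2605 ± 204.5 and 600.1 ± 143 CPM (log2 2.12, SE 0.16, adjusted p = 1.7e-15). MSTN was at 36.7 ± 22.3 and 178 ± 59.3 CPM (log2 -2.35, SE 0.31), IGF2 at 1446.5 ± 651 and 3677 ± 816 CPM (log2 -1.36, SE 0.26) and FST at 5438.5 ± 614 and 3564 ± 347 CPM (log2 0.61, SE 0.08). IL6, higher at the 2 earlier times, fell at 36 h, to 1342 ± 330.0 CPM against 2110.4 ± 181 (log2 -0.66, SE 0.15, adjusted p = 0.000587). Its call at 12 h was kept in 15 of 19 alternative settings and ended without replicate 1 (adjusted p = 0.058). HIF1A, the oxygen-regulated transcription factor whose control is mainly by protein stability, fell by 0.20 (SE 0.07, adjusted p = 0.0414), a call kept in 5 of 19 alternative settings.

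Other rises at 36 h were in the fatty acid receptor FFAR4 (log2 2.09, 1.65 ± 1.88 to 8.45 ± 3.36 CPM), ENSGALG00000041298 (1.64), WNT10A (1.29, kept in 10 of 19 settings), HK2 (1.24), MMP9 (1.23), MYH1E (1.16), PVALB (1.14) and the Wnt antagonist SFRP5 (0.95). Falls were in ELOVL3 (log2 -2.52), CCL5 (-2.49), ENSGALG00000012061 (-2.22), ELOVL4 (-2.01), SPON2 (-1.74), ALPL (-1.62), GPC3 (-1.50) and TNFRSF1B (-1.23). The changes of FFAR4 and CCL5 rest on few reads, as median totals were 706741 counts in normoxia and 651605 in hypoxia. CCL5 in hypoxia was at most 3.74 CPM outside replicate 4. MYOD1 (log2 0.06), MYOG (0.15), PAX7 (0.09), MYF5 (0.42), MYF6 (0.40), PCNA (0.08), CCND1 (0.10), CDKN1A (-0.32), VEGFA (0.09), PDK1 (-0.02), SLC2A1 (0.04) and IGF1 (-0.59) did not pass.

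Of the lists 5 were called on balance at 36 h. Of 11 contractile genes 3 rose, among them MYH1E and PVALB, and 8 did not pass, with 3 adjusted over the list alone (Up, adjusted p = 0.000539). Of 7 identity genes PAX3 (log2 0.86) and NCAM1 (0.28) rose, 2 adjusted over the list alone (Up, adjusted p = 0.0102). The proliferation list was called upward (adjusted p = 0.00418) with 0 of 5 genes passing, also adjusted over the list alone; edgeR gave 2 of the 5 at an unadjusted p under 0.05 and DESeq2 called 0, and E2F1 was at 0.49 and RRM2 at 0.13. The autophagy list was called downward (adjusted p = 0.032) with 0 of 3 passing and 1 lower adjusted over the list alone (1 at an unadjusted p under 0.05, 0 by DESeq2), BECN1 being at -0.30 and MAP1LC3A at -0.14. The stress list was called upward (adjusted p = 0.032) with 0 of 3 passing (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2), EIF2AK3 being at 0.29 and the chaperone HSPA5 at 0.10. The TGF-beta list had 2 of 12 higher and 2 lower, the same adjusted over the list alone (on balance adjusted p = 0.398 with a median of 0.05 and a mean of -0.17, in either direction 0.0377).

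At 36 h 74 of 453 genes changed, 28 higher and 46 lower (121 at an unadjusted p under 0.05). Of these, 62 of the 74 lay on one side of the normoxia mean in 6 of 6 hypoxia libraries. Scaling to reference genes gave 25 higher and 26 lower and left the identity, contractile, proliferation, autophagy and stress lists uncalled (adjusted p = 0.122, 0.191, 0.349, 0.708 and 0.563). A fit of these groups alone called 33 genes and technical replicate 2 alone 39. Of the 6 hypoxia libraries at 36 h, replicate 4 had a total count of 235311 and stood apart in 21 of the values examined. Without it 99 genes were called, 69 of them shared with the 74. When the oxygen levels were exchanged within biological numbers at 36 h, 4 of 32 groupings, the real one included, gave 74 genes or more, up to 114. Leaving out 1 replicate ended the calls of HIF1A (replicate 1, 2, 3, 5 or 6, adjusted p up to 0.204), WNT10A (1, 3, 4 or 6, up to 0.187), NCAM1 (1, 3, 5 or 6, up to 0.108), PAX3 (4, 0.114), TNFRSF1B (3, 0.0798) and ELOVL4 (5, 0.0916). It also ended those of the autophagy (1, 3 or 4, up to 0.169), stress (1, 3 or 6, up to 0.088) and identity lists (2 or 4, up to 0.109).

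At 48 h (n = 6 against 6) FST was at 6294 ± 640.2 CPM in hypoxia and 2806.5 ± 263 in normoxia (log2 1.17, SE 0.08, edgeR adjusted p = 1.27e-16). EXFABP was at 3218.5 ± 169.8 and 736 ± 123.5 CPM (log2 2.13, SE 0.16), COCH at 1709.7 ± 357 and 257 ± 92.1 CPM (log2 2.73, SE 0.27), and HK2, which commits glucose to metabolism, at 1551 ± 433 and 307 ± 46.8 CPM (log2 2.34, SE 0.27). ACACA, the first step of fatty acid synthesis, was at 1716 ± 259.9 and 549 ± 73.5 CPM (log2 1.65, SE 0.21). MSTN stood at 27.0 ± 11.3 CPM in hypoxia and 151 ± 31.3 in normoxia (log2 -2.53, SE 0.32), SPON2 at 91.0 ± 16.2 and 347 ± 36.2 CPM (log2 -1.93, SE 0.21), and BMP2, a bone morphogenetic protein, at 489.9 ± 159.9 and 1379 ± 161 CPM (log2 -1.49, SE 0.25).

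Rises besides these were in WNT10A (log2 2.50, 8.71 ± 5.81 to 55.2 ± 22.6 CPM), CCL20 (2.23), WNT4 (2.17, SE 0.73), ENSGALG00000041298 (1.96), EDN2 (1.67) and MMP9 (1.66). Falls were in ENSGALG00000012061 (log2 -2.61), MC5R (-2.43), TNFRSF1B (-2.29), ALPL (-1.76), GPC3 (-1.75), CCL5 (-1.69), the endothelin receptor EDNRB (-1.42) and IGF2 (-1.01). MC5R, a melanocortin receptor, is 1 of the 17 co-varying genes. MYOD1 (log2 -0.02), MYOG (0.04), PAX7 (-0.18), MYF5 (0.35), MYF6 (0.12), PCNA (0.01), CCND1 (0.07), CDKN1A (-0.17), HIF1A (-0.16), VEGFA (0.02), PDK1 (-0.08), SLC2A1 (0.26, adjusted p = 0.0681) and IGF1 (-0.35) did not pass.

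The test called 7 lists on balance at 48 h. Of 6 FGF and PDGF receptors 2 rose and 4 did not pass (3 higher adjusted over the list alone; Up, adjusted p = 0.000561), led by FGFRL1, a decoy-like FGF receptor (log2 0.65, SE 0.08), with FGFR3 at 0.51 (adjusted p = 0.151). Of 11 glycolysis genes HK2 rose and 10 did not pass, 1 adjusted over the list alone (Up, adjusted p = 0.00196), with ENO1 at 0.73 (adjusted p = 0.0709). Of 3 autophagy genes BECN1 (-0.41) and MAP1LC3A (-0.14) fell (3 lower adjusted over the list alone; Down, adjusted p = 0.00386). Of 11 contractile genes 2 rose, MYH1E (1.34, SE 0.12) and PVALB (1.28), 2 fell, MYH1F (-0.86, SE 0.18) and MYH1D (-0.18, SE 0.07, adjusted p = 0.049), and 7 did not pass, the same adjusted over the list alone (Up, adjusted p = 0.00398; either direction 0.000103). TNNT2 was at 1.38 (adjusted p = 0.284). Of 5 proliferation genes RRM2 rose (0.15, SE 0.05), 1 adjusted over the list alone (Up, adjusted p = 0.0105), with E2F1 at 0.18. Of 7 identity genes PAX3 (0.92) and NCAM1 (0.36) rose, 2 adjusted over the list alone (Up, adjusted p = 0.0495). In the TGF-beta list 2 of 12 rose and 2 fell, the same adjusted over the list alone, and the call was upward (adjusted p = 0.0495; either direction 3.72e-08) with a median of 0.08 and a mean of -0.17, FST and MSTN again moving apart.

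At 48 h 101 of 453 genes changed, 59 higher and 42 lower (134 at an unadjusted p under 0.05). Of these, 93 of the 101 lay on one side of the normoxia mean in 6 of 6 hypoxia libraries, with WNT4 in 5 and BECN1 in 4. The libraries above the gap in the 17-gene score were 5 of 6 in normoxia and 2 of 6 in hypoxia. Without them, with 1 normoxia library left, 22 genes were called and the identity, contractile, proliferation, glycolysis, FGF and autophagy lists were not (adjusted p = 0.805, 0.816, 0.957, 0.805, 0.805 and 0.195). The TGF-beta list changed direction without those libraries (adjusted p = 0.822) and without replicate 1 (0.947). With reference-gene scaling it was not called (0.876) and neither were the other 6 lists (0.666 each). RRM2 kept its call in 4 of 19 alternative settings, and the identity list in 3 of 18. Leaving out 1 replicate ended the calls of RRM2 (replicate 1, 2, 3 or 5, adjusted p up to 0.263), BECN1 (1, 3, 4 or 5, up to 0.142), MAP1LC3A (3, 4 or 6, up to 0.17), WNT4 (1, 2, 3 or 5, up to 0.149), CCL5 (1, 3, 4 or 5, up to 0.14), ALPL (1 or 5, up to 0.081) and MYH1D (3, 4 or 6, up to 0.22). Among the lists it ended those of identity (each of the 6, up to 0.258), proliferation (1, 2 or 5, up to 0.426), contractile genes (1 or 5, up to 0.17), glycolysis (5, 0.0905) and TGF-beta (2, 3 or 5, up to 0.726).

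**Figure D3:**
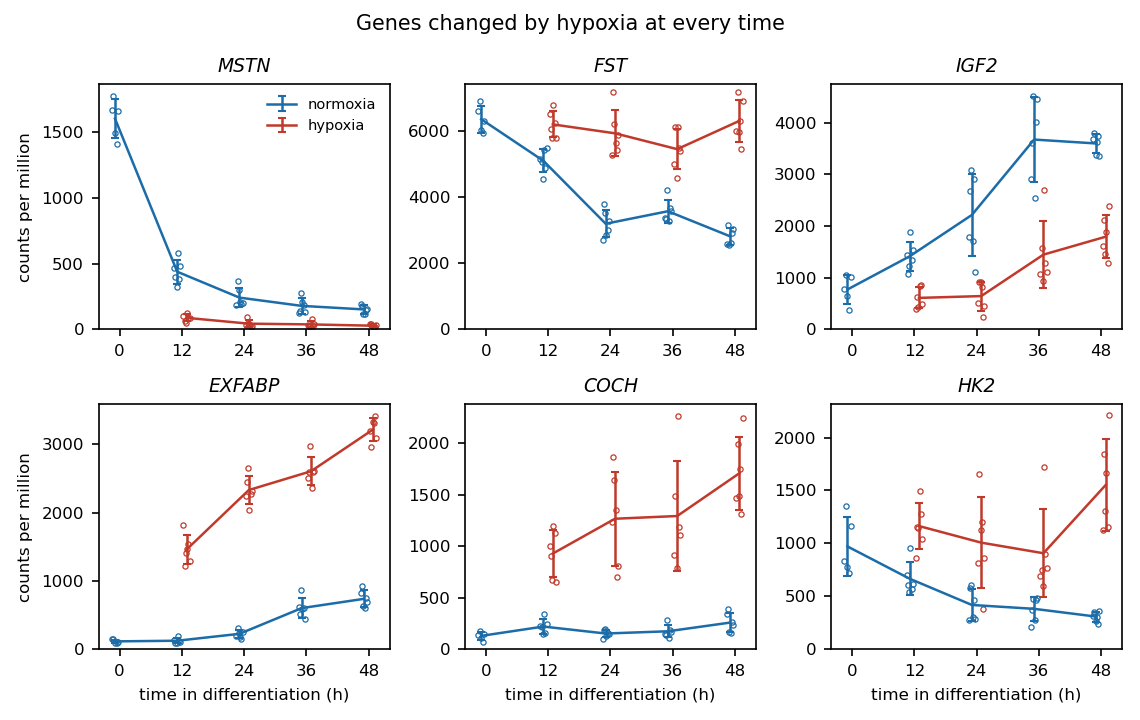
Normalised read counts (CPM, vertical axis) against hours in differentiation (horizontal axis) for genes called at every harvest, with points for libraries, lines for group means and bars for the SD, normoxia in blue and hypoxia in red. EXFABP rose to 3218.5 CPM in hypoxia and 736 CPM in normoxia at 48 h, and MSTN fell to 27.0 and 151 CPM.

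Some lists gave no call on balance at any of the 4 times under hypoxia. For the HIF pathway list the adjusted p was 0.073 at 12 h, 0.133 at 24 h, 0.398 at 36 h and 0.26 at 48 h, and BHLHE40 was its one member higher at every time, with log2 changes of 0.24, 0.31, 0.27 and 0.41. The myogenic regulatory factors gave 0.546, 0.123, 0.398 and 0.877, Notch signalling 0.144, 0.409, 0.689 and 0.26, and IGF and insulin signalling 0.12, 0.533, 0.398 and 0.666. Matrix and fibroblast genes gave 0.073, 0.64, 0.498 and 0.718, antioxidant genes 0.0759, 0.0838, 0.465 and 0.877, and apoptosis genes 0.0759, 0.103, 0.454 and 0.718. Of 7 tested reference genes 0 passed in any of these contrasts or from 0 to 48 h (2 at an unadjusted p under 0.05 at 12 h and 0 elsewhere, 0 by DESeq2). The fusion list had 2 tested members, and CAV3 (log2 -0.02, adjusted p = 0.903) and GRB2 (-0.04, 0.767) did not pass at 48 h.

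Over the 4 times, 173 genes were called at 1 time or more and 23 at every time. The 12 that were higher at every time were EXFABP, COCH, FST, HK2, BHLHE40, MYH1E, PVALB, NCAM1, the interleukin receptor subunit IL10RB, RBP4A, the glucose transporter SLC2A14 and the matrix glycoprotein THBS1. The 11 that were lower were MSTN, IGF2, TNFRSF1B, ALPL, GPC3, ENSGALG00000012061, WNT5A, DPT, the kinase MAPK11, the protease TLL1 and the malate dehydrogenase MDH2. The falls of TNFRSF1B and ALPL rest on few reads. In hypoxia TNFRSF1B was at 12.7 CPM in replicate 2 at 48 h and at most 4.19 CPM in the others. ALPL at 36 h was at 20.6 CPM in replicate 2 and at most 6.73 CPM in the others. When each replicate was left out in turn, 14 to 19 of the 23 were called at every time, and 12 were in all 6 of these fits: EXFABP, COCH, MYH1E, PVALB, RBP4A, MSTN, IGF2, GPC3, ENSGALG00000012061, WNT5A, DPT and MDH2. Of the 23, 13 were called at every time with reference-gene scaling, 13 and 14 with technical replicate 1 or 2 alone, 15 in fits of the compared groups alone, and 7 without the libraries above the gap in the 17-gene score. Calls of neighbouring times, which share no libraries, overlapped more than independent lists would. The overlap was 17 genes higher at both 12 and 24 h against 3.4, and 28 lower at both 36 and 48 h against 4.3. However, the times share 1 fit of the spread, and the expected numbers give every gene the same chance of a call. Part of the excess may come from that, so it does not measure independent agreement.

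A direct test asked whether the effect of hypoxia differed between 12, 24, 36 and 48 h, and 48 of 453 genes passed (102 at an unadjusted p under 0.05). The 6 with the smallest p were IL6, the immediate early factor EGR1, SPON2, EXFABP, FST and NPY. IL6 had log2 changes of 0.59, 1.61, -0.66 and 0.00 at the 4 times (adjusted p of the difference 4.2e-11), and EGR1 of 0.35, 0.08, -0.57 and -0.32 (1.81e-09), where the change at 24 h did not pass on its own. SPON2 had 0.46, -2.29, -1.74 and -1.93 (7.01e-09), the first not passing, and EXFABP 3.60, 3.41, 2.12 and 2.13 (2.01e-08). FST had 0.28, 0.90, 0.61 and 1.17 (1.84e-07), as its normoxia level went from 5085 ± 350.4 CPM at 12 h to 2806.5 ± 263 at 48 h. NPY had -1.43, -0.80, 0.08 and 0.33 (5.78e-06), the last 2 not passing, and its normoxia level went from 2003 ± 243 to 889.6 ± 125 CPM. The count was 22 with reference-gene scaling, 30 and 25 with technical replicate 1 or 2 alone, 31 without replicate 3, and 13 without the libraries above the gap in the 17-gene score.

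**Figure D4:**
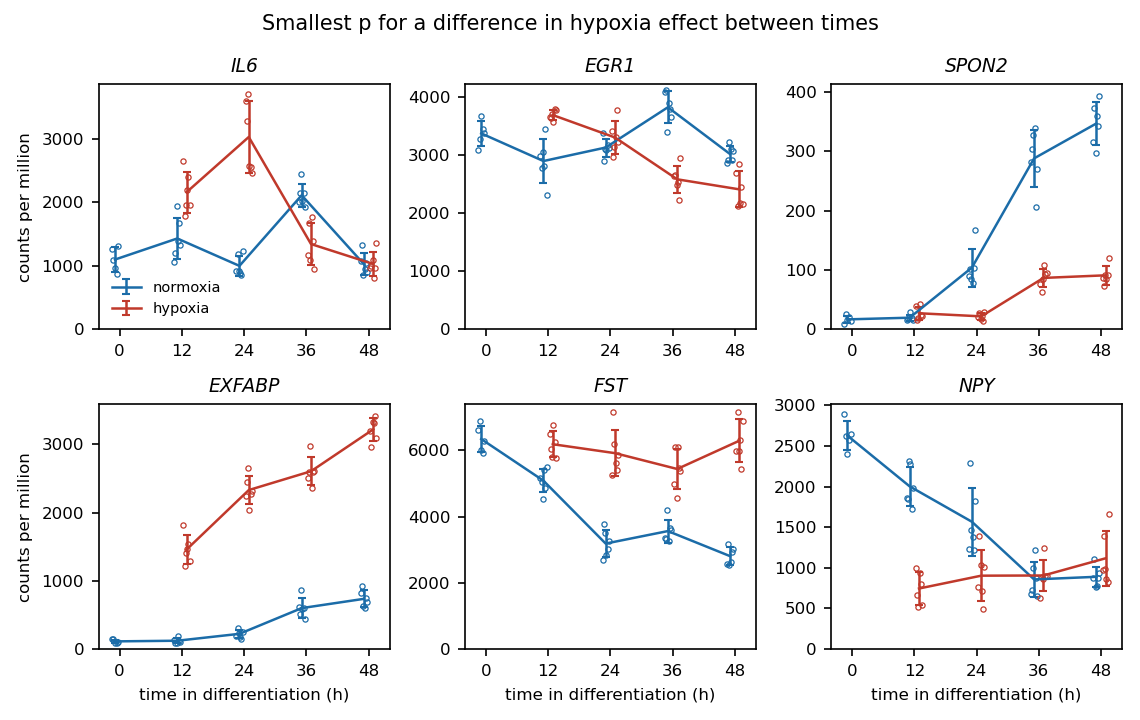
Normalised read counts (CPM, vertical axis) against hours in differentiation (horizontal axis) for the 6 genes with the smallest p in the test of a difference in the hypoxia effect between times, with points for libraries, lines for group means and bars for the SD, normoxia in blue and hypoxia in red. IL6 peaked at 3028 CPM at 24 h in hypoxia and at 2110.4 CPM at 36 h in normoxia.

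The course under hypoxia was compared in the same way, 48 h of hypoxia (n = 6) with the 0 h libraries (n = 5). EXFABP rose from 113 ± 26.1 to 3218.5 ± 169.8 CPM (log2 4.85, SE 0.19, adjusted p = 6.34e-27) and COCH from 128 ± 39.4 to 1709.7 ± 357 CPM (log2 3.74, SE 0.31). MSTN fell from 1604 ± 147 to 27.0 ± 11.3 CPM (log2 -5.94, SE 0.36). PTGDS (log2 3.64), the G protein regulator RGS4 (3.06), the matrix protein SPARC (3.01) and CCL20 (2.79) rose, and EDNRB (-3.73), ELOVL3 (-3.33), GPC3 (-3.21), TNFRSF1B (-3.06) and EDN1 (-2.83) fell. FST did not pass (log2 -0.01, adjusted p = 0.92). IGF1 fell by 2.33 and IGF2 rose by 1.22 on the log2 scale, and HIF1A fell by 0.26 and PCNA by 0.20. MYOD1 (-0.09), MYOG (0.02), PAX7 (-0.24), MYF5 (-0.50, adjusted p = 0.0521) and MYF6 (-1.09) did not pass. In all 200 of 453 genes changed, 86 higher and 114 lower (224 at an unadjusted p under 0.05), and 186 lay on one side of the 0 h mean in 6 of 6 libraries. No alternative moved that count by more than 1.5 times.

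Of 11 contractile genes 7 rose, 1 fell and 3 did not pass, the same adjusted over the list alone (Up, adjusted p = 1.05e-20), led by LDB3 (log2 2.10) and PVALB (1.97). Of 3 inhibitors of myogenic factors MSTN and HEY1 (-2.17) fell and 1 rose, the same adjusted over the list alone (Down, adjusted p = 1.02e-16). Of 7 identity genes ITGA7 rose (2.22) and 3 fell (4 adjusted over the list alone; Down, adjusted p = 0.000211), CD34 by 1.37. Of 5 proliferation genes 3 fell, also adjusted over the list alone (Down, adjusted p = 2.28e-08), E2F1 by 2.00. In the Wnt list 1 of 7 rose and 3 fell, the same adjusted over the list alone (Down, adjusted p = 1.64e-08), with WNT4 at -2.43 and WNT5B at -1.44, and 2 of 3 Notch genes fell, also adjusted over the list alone (Down, adjusted p = 4.41e-07), with NOTCH1 at -2.06. Of 22 lipid genes 8 rose, also adjusted over the list alone (Up, adjusted p = 1.2e-07), led by ACACA (2.18) and APOA1 (1.89). In glycolysis 2 of 11 rose, ENO1 (1.09) and HK2 (0.68), 1 adjusted over the list alone (Up, adjusted p = 0.000162).

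Of the remaining lists over 48 h of hypoxia, 2 of 3 autophagy genes fell, BECN1 (log2 -0.73) and MAP1LC3A (-0.17), 2 adjusted over the list alone (Down, adjusted p = 0.000171). Of 7 antioxidant genes TXNRD1 (-1.22) and MT3 (-0.54) fell, 2 adjusted over the list alone (adjusted p = 1.41e-05). Of 4 endothelial, immune and blood cell markers VWF (-2.53) and CDH5 (-1.36) fell, 2 adjusted over the list alone (adjusted p = 1.41e-05). FAS (1.03) was the 1 of 5 apoptosis genes that rose, 1 adjusted over the list alone (Up, adjusted p = 0.00275), with CASP6 at -0.26. The TGF-beta list had 4 of 12 higher and 4 lower, the same adjusted over the list alone (Down, adjusted p = 0.00679, mean -0.61, median 0.05), TGFB1 falling by 1.33. Scaling to reference genes ended the TGF-beta, autophagy, antioxidant and apoptosis calls (adjusted p = 0.888, 0.116, 0.344 and 0.193), and the TGF-beta call was also lost without the libraries above the gap in the 17-gene score (0.0978), with the biological number as a replicate block (0.0513) and without replicate 6 (0.0648). No call on balance came from the HIF pathway (adjusted p = 0.118), mitochondrial (0.118), IGF and insulin (0.562), FGF and PDGF (0.455), matrix (0.405), stress (0.405) or myogenic factor (0.313) lists, although the mitochondrial, IGF and matrix lists changed in either direction (4.03e-11, 0.0018 and 0.00129). Leaving out 1 replicate ended the calls of HK2 (replicate 1, 3, 4 or 6, adjusted p up to 0.119), CD34 (2, 3 or 5, up to 0.251), CDH5 (1, 2 or 5, up to 0.0873) and MAP1LC3A (3, 0.0534).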

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

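Of the tests on the 17-gene set, those on genomic DNA and on biological number 1 were chosen after the result was seen, as were the set itself and the limit of the marker test to tested genes. Each value named is the highest or lowest of its group of 5 or 6 libraries, apart from the others by more than Dixon's 95% limit. Over 954 groups of values 84 were apart. Independent, normally distributed values would give about 1 in 20, or 47.7. The CPM were not put on a log scale, the genes share libraries, and most were chosen because they were called. An excess over chance is therefore not shown. The values apart fall in 57 of the quantities examined, which are 104 genes, the total count and the score. The score is among the 57, and 25 of the 84 values lie in libraries with the 17 genes raised.

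The score of the 17 genes was highest in replicate 1 of normoxia at 36 h (8.3) and of hypoxia at 12 h (9.14), 24 h (9.29) and 36 h (8.96). Libraries of biological number 1 made up 8 of the 17 raised libraries (8 of 9 against 9 of 44 with other numbers, Fisher exact p = 0.000203, two-sided), but the 9 raised libraries with another number argue against number 1 as the whole cause. For endothelial, immune or blood cells in the culture, the 4 tested markers had a median within-group correlation with the score of 0.073, under the bound of 0.1 set beforehand, but that bound was wrong for markers that go both ways (VWF -0.164, IL10 0.406), and with the other 3 of 7 too low to be tested this stays open. Genomic DNA may contribute, since 5 of the 17 genes have a single exon against 4 of 436 others (Fisher exact p = 4.58e-06). But 12 of the 17 have more exons. The 3 tested nuclear single-exon genes outside the set, too few to decide, correlated with the score by -0.554 to 0.308, so genomic DNA stays open. Beyond other cells in the culture, no biological explanation was tested.

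In hypoxia at 36 h, replicate 4 had the highest levels (CPM) of ACACA (1510.2), CAPN3 (383.5), CCL5 (12.0), CD34 (12.0), CDKN1A (2868.6), E2F1 (1502.2), ELOVL1 (251.7), ENSGALG00000025996 (1042.8), ENSGALG00000041298 (191.8), HEY1 (727.1), HK2 (1726.0), IGF2 (2696.8), ITGA7 (950.9), MAPK11 (511.4), MMP9 (511.4), MSTN (79.9), MYLK (343.6), NOTCH1 (507.4), SFRP5 (2624.9) and TLL1 (918.9), and the lowest of MYOD1 (3188.2). In the same group replicate 1 was highest for BMP2 (1255.1) and MC5R (691.6) and lowest for KLF6 (1599.9) and LDB3 (2658.7), replicate 2 was highest for ALPL (20.6), and replicate 6 for MYH1F (160.9).

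In hypoxia at 12 h, replicate 1 was highest for MC5R (700.3) and lowest for KLF6 (2142.1), RASD1 (852.3) and WNT5B (1161.4). Replicate 4 was highest for CAPN3 (350.3) and ENSGALG00000025996 (949.7), replicate 5 for NOTCH1 (613.7) and TGFB1 (492.4), and replicate 6 was lowest for APOA1 (933.3). In hypoxia at 24 h, replicate 1 was highest for BMP2 (1532.5), MC5R (829.1) and WNT5B (1345.6), replicate 2 for EDN1 (100.2), ENSGALG00000012061 (219.6), PVALB (304.3) and VWF (273.5), and replicate 6 for KLF9 (48.7). In hypoxia at 48 h, replicate 2 was highest for EDNRB (84.9), RRM2 (4889.5) and TNFRSF1B (12.7), replicate 3 for IL10RB (3896.7), and replicate 6 for MC5R (289.1) and TGFB1 (509.2) and lowest for PDK1 (2938.6).

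In normoxia at 0 h, replicate 1 was highest for MC5R (325.2) and replicate 2 for MYH1D (1801.4). At 12 h, replicate 4 was highest for CCL5 (76.3), CD34 (50.9), CDH5 (35.0), FGF18 (111.3) and SPON2 (28.6) and lowest for BHLHE40 (2010.3) and MYOG (3960.1), replicate 5 was highest for PAX7 (9730.6) and RGS4 (162.8) and lowest for ENSGALG00000030587 (41.4), and replicate 6 was highest for MYH1D (4353.7). At 24 h, replicate 2 was highest for DPT (2669.8) and FGF18 (185.3) and lowest for WNT5A (2096.1), replicate 3 was highest for ENSGALG00000041298 (43.8), and replicate 6 for BMP2 (1388.4) and SPON2 (166.8). At 36 h, replicate 1 was lowest for KLF6 (1901.6), and the highest values were in replicate 2 for COL12A1 (53.0), replicate 3 for FGF18 (405.2), replicate 4 for CDH5 (47.7), EDN1 (83.4), PCNA (7355.2) and SLC2A14 (4816.0), and replicate 6 for ACACA (730.1). At 48 h, replicate 2 was highest for RBP4A (1259.7) and VWF (105.0).

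A test of the difference itself found that the effect of hypoxia differed between the 4 times for 48 genes. Its 6 smallest adjusted p-values (edgeR) were those of IL6 (4.2e-11), EGR1 (1.81e-09), SPON2 (7.01e-09), EXFABP (2.01e-08), FST (1.84e-07) and NPY (5.78e-06).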

How the results depend on the processing

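The settings that leave out or adjust for the 17-gene set, that take each transcript alone or that leave out hypoxia 36 h replicate 4 were chosen after seeing the data. Of 254 single-gene results 139 kept direction and call in each setting that gave them a value (130 in all 19, and 9 in the 16 to 18 in which their gene was tested) and 115 did not. Of 49 list results 17 kept theirs in all 18 settings run for lists (DESeq2 was not run for them) and 32 did not. Leaving out 1 biological number at a time gave 44 to 86 genes at 12 h, 59 to 69 at 24 h, 54 to 91 at 36 h, 85 to 101 at 48 h, 31 to 48 for the difference between times, 153 to 174 from 0 to 48 h in normoxia, 170 to 205 in hypoxia, and 208 to 259 over time. Scaling to reference genes gave 42 genes at 12 h and 22 for the difference between times. Technical replicate 1 alone gave 47 at 12 h, 55 at 24 h and 30 for the difference, and replicate 2 alone 49 at 24 h, 39 at 36 h and 25 for the difference, settings that hold fewer reads. A fit of the compared groups alone gave 131, 42 and 33 genes at 12, 24 and 36 h. Without the libraries with the raised set, which leaves 1 normoxia library at 48 h that is assumed to vary like the other groups, the counts were 24 at 12 h, 22 at 48 h, 13 for the difference, 68 from 0 to 48 h in normoxia and 147 over time, of which 23, 22, 13, 67 and 141 were shared with the genes called on all libraries. Of the 184 genes called from 0 to 48 h in normoxia 3 had the other direction without those libraries, CDH5 (log2 0.36), KLF6 (0.03) and NFKBIA (0.00), none of them then called. Direction also changed for the TGF-beta list at 48 h of hypoxia without them (adjusted p = 0.822) and without replicate 1 (0.947; 0.0163 to 0.947 over the replicates left out). Without hypoxia 36 h replicate 4 the counts were 99, 92, 99 and 102 at the 4 times, 57 for the difference, 190 and 210 from 0 to 48 h and 283 over time. For the settings that do not remove samples, the cause was not tested. The biological number as a replicate block gave 110, 85, 78 and 108 genes at 12, 24, 36 and 48 h, 55 for the difference, 196 and 209 from 0 to 48 h and 295 over time. Of 24 same-numbered pairs 12 correlated above 0.1 (-0.32 to 0.78). Among the 6 normoxia libraries of its time, 7 hypoxia libraries correlated best with their own number. These values do not settle whether the numbers pair the samples, and the labels do not say so. The main tests therefore do not pair them. Total counts did follow the number: the 6 hypoxia and 6 normoxia libraries with low totals (up to 296563, against 516809 or more in the others from 12 h on) had the same numbers at the same times, and in the other 18 pairs log2 totals, less the group mean, correlated by r = 0.90 (permutation p = 4e-05, two-sided) and rho = 0.86 (p = 1e-04), r = 0.87 without the 2 hypoxia libraries farthest from the median. Libraries with the same number may therefore share handling within a time. The main tests leave this out, and no fit paired libraries by number within a time alone. The low totals carried number 4 at 12 and 36 h but numbers 2 and 6 at 24 and 48 h. At 0 h the lowest total (311436) carried number 2. A number may thus not mark the same thing at every time, as the block and the fits without 1 number assume. On the other side, 8 of the 9 libraries with number 1 had the 17 genes raised, against 9 of 44 with other numbers. Handling that differed between harvests cannot be told apart from time in any comparison between times, 36 h with 0 h among them.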

Other observations

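The test of the delayed course and its check against the 17-gene set were set down before their results were seen, while the tests on fold size at high counts, the regroupings within biological numbers and the genes described here were chosen after. Of the genes called at every time under hypoxia, the interleukin 10 receptor subunit IL10RB was higher by 0.37, 0.29, 0.29 and 0.47 (log2) at 12, 24, 36 and 48 h, the retinol carrier RBP4A by 0.92, 0.86, 0.64 and 0.76, the glucose transporter SLC2A14 by 0.27, 0.18, 0.16 and 0.22, and THBS1, thrombospondin, by 0.17, 0.49, 0.24 and 0.47. Lower at every time were the matrix protein DPT (-0.60, -0.99, -1.15 and -1.03), the stress kinase MAPK11 (-0.99, -0.63, -0.83 and -1.02), malate dehydrogenase MDH2 (-0.59, -0.78, -0.74 and -0.75) and the protease TLL1 (-0.83, -0.71, -0.93 and -0.96). The calls ended without 1 replicate were those of THBS1 at 12 h (1, 2, 3 or 5, adjusted p up to 0.134), SLC2A14 at 24 h (3, 5 or 6, up to 0.228) and 36 h (1, 2, 3, 5 or 6, up to 0.294) and IL10RB at 24 h (1 to 5, up to 0.0804) and 36 h (3, 5 or 6, up to 0.142). Others were those of MAPK11 at 24 h (1, 3, 4, 5 or 6, up to 0.114) and 36 h (3, 0.0626) and TLL1 at 24 h (5, 0.0548).

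Of the genes called at 2 or more times 8 were called in both directions. Besides IL6 and EGR1, HEY1 was lower at 12 h (-0.64) and higher at 48 h (0.85, adjusted p = 0.00124), and ENSGALG00000025996 was lower at 12 h (-0.67) and higher at 36 and 48 h (0.93 and 1.23). The phosphatase DUSP5 was higher at 12 and 24 h (0.28 and 0.43) and lower at 36 h (-0.36), and KLF6 likewise (0.18, 0.21 and -0.19). RASD1 was higher at 12 h (0.61) and lower at 24 h (-0.55), and SESN1, a stress-induced inhibitor of growth signalling, was higher at 12 h (0.29), lower at 24 h (-0.27) and higher at 48 h (0.55). In the 19 alternative settings KLF6 kept its calls at 12, 24 and 36 h in 4, 14 and 8, DUSP5 in 9, 19 and 16, RASD1 at 12 and 24 h in 13 and 12, and SESN1 at 12, 24 and 48 h in 8, 6 and 18. Without 1 replicate the calls ended for KLF6 at 12 h (each of the 6, adjusted p up to 0.119), 24 h (4, 0.0529) and 36 h (1, 2, 3 or 6, up to 0.108), and for DUSP5 at 12 h (2, 3, 4 or 6, up to 0.143). They also ended for ENSGALG00000025996 at 12 h (2, 3 or 6, up to 0.143), HEY1 at 12 h (1, 2, 3 or 6, up to 0.104), RASD1 at 12 h (2, 3 or 6, up to 0.144) and 24 h (3, 5 or 6, up to 0.296) and for SESN1 at 12 h (1, 2, 3, 4 or 6, up to 0.219) and 24 h (2, 3, 4 or 6, up to 0.173).

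Genes that moved during the normal course were compared with those changed by hypoxia at 48 h, using 36 h against 0 h in normoxia so that no library was shared. Of 57 genes changed in both, 42 (73.7%) moved in opposite directions (one-sided Fisher exact p = 0.00115). Of these, 14 rose in normoxia and were lower under hypoxia, among them SPON2, DPT and IGF2. The other 28 fell and were higher, among them FST, HK2, PAX3 and WNT4. The 28 also include the endothelial marker VWF (log2 -3.41 from 0 to 36 h, 1.11 under hypoxia), so they are not all muscle genes. The other 3 tested markers of other cells did not pass under hypoxia at 48 h. With the score of the 17 genes as a covariate the share was 71.2% (one-sided Fisher exact p = 0.00252). This argues against that set as the whole cause only as far as a covariate can adjust for it. The set was raised in 5 of 6 normoxia and 2 of 6 hypoxia libraries at 48 h, and the share was not computed without them. The set is therefore not excluded. Both Fisher tests take genes as independent, which genes measured in the same libraries need not be. Genes that had fallen to few counts in normoxia, such as WNT10A, also had little room to be called lower under hypoxia. This may favour opposite directions without any delay, although 8 genes fell and were lower. A delayed course of differentiation under hypoxia may be a candidate explanation, as a hypothesis. The other 15 genes moved in the same direction in both. A delay alone would not give this for a gene that moves one way up to 48 h in normoxia. Whether each of the 15 does so was not tested. The 15 include MSTN, EXFABP and the muscle genes MYH1E (0.47 from 0 to 36 h, 1.34 under hypoxia) and PVALB (0.82 and 1.28).

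Genes with high counts changed little. After the squared SE was taken off, the root mean square log2 change from 0 to 48 h in normoxia was 1.41, 0.98 and 0.25 in the low, middle and top group of 151 genes each by CPM, and 0.84, 0.56 and 0.15 for hypoxia at 48 h. The ratio of middle to top group, 3.92, argues against larger noise at low counts as the cause. A readout compressed at high counts could give the value of 0.25 in the top group, and stays open because no second assay was used here. MYOD1, MYOG and PAX7 are in the top group, so their lack of calls may reflect such a readout. No biological explanation was tested.

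Regrouping the libraries of each comparison at random without regard to the biological number, 100 groupings with the real one, gave fewer than 5 groupings with as many genes for each count. At 12 h 1 grouping, the real one, gave as many genes (81, highest other 18), at 24 h 3 (84, 93), at 36 h 4 (74, 89) and at 48 h 1 (101, 47). For the difference between times it was 1 (48, 16), from 0 to 48 h 1 in normoxia (184, 91) and 1 in hypoxia (200, 192), and over time 1 (271, 116). The 24 h groupings with 93 and 89 genes exchange 1 library between the real groups, while a 24 h grouping with 75 genes and 36 h groupings with 78 and 77 keep 3 of 6 together, which points to a structure among the libraries of both times whose cause was not tested. Since totals follow the biological number, the oxygen levels were also exchanged within numbers, in 32 groupings at each time. Only the real one, 1 of 32, reached its count at 12 h (highest other 24), 24 h (47) and 48 h (53), while 4 of 32 did at 36 h (share 0.125, highest other 114). The share was thus under 0.05 in both ways at 12, 24 and 48 h but not at 36 h. With 32 groupings the lowest possible share is 0.0312, and no allowance was made for testing 4 times, so chance is not excluded. A count also does not show which of its genes changed. The other 4 counts were not tested within numbers.

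PCYT2, chosen after its values were seen, had 0 counts in both technical replicates of 10 libraries and in 1 replicate of 8 more, with up to 457 counts in the other, and more than 100 CPM in 41 libraries.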
